A study of Mus musculus with 7 samples.

How the data were processed

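The 7 libraries were 5C libraries of V6.5 mouse embryonic stem cells in 2i medium, made from HindIII 3C templates with double alternating primers over 5 regions, 1 from a dilution template and 6 from in situ templates. Per the submitters' processing notes, reads were aligned with Bowtie (no version given) and positions are in mm9. The deposited raw files held the count of each primer pair, as whole numbers. The deposited maps held a signal for each 4-kb bin pair, which per the file names the authors smoothed over 6 kb, balanced (iced) and normalized. The authors deposited 1 joint set with the dilution and in situ 200k libraries and 1 joint set with the 6 in situ libraries, and values were compared within a set. Within a set the summed signal of a region differed between libraries by at most 6.2e-12% and its median by at most 0.013%, so the maps cannot show a difference in level. The exception to comparing within a set was the correlation of the in situ maps with the dilution map and the use of the dilution clusters in the in situ maps, which cross the sets. The authors also deposited a p-value for each bin pair, computed from the observed signal over a donut-shaped expectation with an inner width of 5 and an outer width of 30 bins, per the file names. The deposited score equalled −10 times log2 of that p-value, with a largest difference of 5.3e-10 over 10678070 values, and was not used further. A further dilution map, which the authors scaled on its 75th percentile alone, was read separately.

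Each count was assigned to a class from its primers: the same fragment, the same region with 1 forward and 1 reverse primer of different fragments, the same region with primers of the same direction, or different regions. The inter-region share of all counts and the detected pairs include primers of the same direction. Possible pairs were counted from the primer list, with 1433779 intra-region pairs of different fragments and 3727908 inter-region pairs. Detection was compared after random thinning, with a fixed seed, to the smallest intra-region total of 7758477 counts. For map correlations each value was divided by the mean of its region at the same distance, and the Spearman rho was taken across bin pairs. Enrichment was log2 of a value over its distance mean, scaled by the observed over expected signal of the donut. Clusters joined bin pairs with the authors' p under 0.01 at 40 kb or more over 8 neighbours, with at least 3 bin pairs. Overlap was compared with 100 random shifts along the diagonal. The 3 clusters with the lowest p per region and library were named. Shares carry 95% Wilson intervals and the median difference a bootstrap interval from 1000 draws of the clusters. Intervals over clusters treat the clusters of a library as independent. Clusters often shared a bin, so these intervals can be too narrow.

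No test between dilution and in situ was run, since the dilution protocol has 1 library and no replicate. Trends over the 6 in situ libraries used Spearman's rho with a two-sided exact permutation test over all 720 orders, with Pearson's r on log10 genome copies beside it, and Benjamini-Hochberg adjustment over 7 measures at a threshold of 0.05. The smallest exact permutation p that Spearman's rho can give is 0.0028 with 6 libraries and 0.0167 with 5. The groups, measures, cluster rule and most alternatives were fixed before the data were examined. The alternatives were other p thresholds, cluster sizes, distances and overlap rules, a minimum of 2 counts, maps without distance correction or from raw counts, another donut, and each in situ library left out. Restriction to forward and reverse pairs of different fragments and enrichment relative to the median bin pair were added after the data had been seen.

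The depth was 22484170 to 41282750 counts per library, and 2269639 to 3602016 primer pairs had a count. On simulated maps of 300 bins, the code was tested with 30 planted contacts each of log2 enrichment 1, 2 and 3 and gave medians of 0.94, 1.88 and 2.70. It returned 5 of 5 planted clusters, and independent calls overlapped in 9.01% against 7.32% after shifts. The planned measurement of promoter contacts was left out, because the gene annotation at hand was on another build than the maps and no coordinates were converted; genes are given by name and neighbours only. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.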

Results

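The libraries measured DNA contacts in V6.5 mouse embryonic stem cells, a male 129SvJae x C57BL/6 line, grown in 2i medium with LIF. Chromosome conformation capture carbon copy (5C) counts junctions between restriction fragments with primers placed at fragment ends. The primers covered 5 regions around genes active in pluripotent cells, in mm9 coordinates. The Sox2 region spanned chromosome 3 from 33510317 to 35746316, with Sox2, a pluripotency transcription factor, between its protein-coding neighbours Dnajc19 and Atp11b. The Klf4 region spanned chromosome 4 from 53455137 to 57043136, with the transcription factor gene Klf4 between Rad23b and Actl7b. The Dppa2 region spanned chromosome 16 from 47900556 to 49196555, with Dppa2 between Dppa4 and Morc1. The Zfp42 region, which the labels call Rex1, spanned chromosome 8 from 44003236 to 45295235, with Zfp42 between Triml2 and Adam26b. The Nanog region spanned chromosome 6 from 122125032 to 122913031, with the transcription factor gene Nanog between Dppa3 and Slc2a3. In the dilution library the 3C template came from lysed nuclei in dilute solution, and in the in situ libraries it was ligated inside intact nuclei.

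There were 7 libraries, with 1 library per group and no replicates. The dilution library started from 200000 genome copies. The in situ libraries started from 200000, 100000, 50000, 10000, 5000 and 1000 genome copies and are called the in situ 200k, 100k, 50k, 10k, 5k and 1k libraries. The total was 28882874 counts in the dilution library, and 41282750, 32806397, 38441595, 34767934, 31180309 and 22484170 counts in the in situ libraries in order of falling input. The 95% Wilson intervals of the shares of raw counts and primer pairs given here reached at most 0.1 percentage points to either side. They cover the counting error of reads only and not that of ligation products, since PCR reads are not independent molecules.

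The comparison of the dilution library with the in situ 200k library asked how the products of the 2 protocols differ at equal input. In all 5 regions most intra-region counts of the dilution library joined the ends of a single fragment, and few did in the in situ 200k library. Such same-fragment pairs held 73.7% of the intra-region counts at Sox2 in the dilution library and 1.83% in the in situ 200k library. The shares were 71.1% and 1.91% at Klf4, 79.7% and 2.48% at Dppa2, 77.5% and 2.87% at Zfp42, and 81.8% and 3.42% at Nanog. Over all counts, same-fragment pairs held 62.6% in the dilution library and 1.93% in the in situ 200k library. The intra-region counts that joined 1 forward and 1 reverse primer of different fragments came to 5920215 in the dilution library and 36696828 in the in situ 200k library.

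Pairs of primers from different regions held 15.8% of all counts in the dilution library and 8.77% in the in situ 200k library, a difference of 7.06 percentage points. The difference was 30.5 points among forward and reverse pairs of different fragments, where the shares were 38.8% and 8.28%. It was 51.1 points without the 1% of pairs with most counts and 12.5 points with each detected pair counted once. Among the forward and reverse pairs that touched a region, the inter-region share was 56.6% in the dilution and 15.6% in the in situ 200k library at Sox2, and 47.1% and 11.8% at Klf4. It was 66.3% and 20.6% at Dppa2, 63.2% and 20.8% at Zfp42, and 69.9% and 22.1% at Nanog. With 1 library of each at this input, neither difference was set against a spread between replicates.

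**Figure D1:**
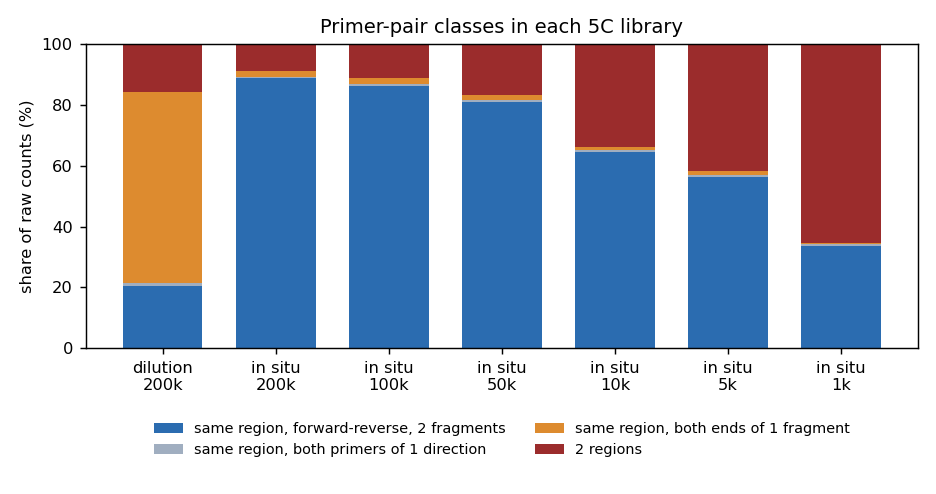
Bars show the share of raw counts (%) of each of the 7 libraries in 4 classes of primer pair. Same-fragment pairs (orange) hold 62.6% of the dilution library and at most 1.93% of an in situ library, and inter-region pairs (red) hold from 8.77% in the in situ 200k library to 65.5% in the in situ 1k library.

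Contacts at a distance stood further above the inter-region level in the in situ 200k library. The mean count per possible intra-region pair, relative to that per inter-region pair, was 153-fold in the dilution library and 504-fold in the in situ 200k library for separations under 20 kb. It was 5.52-fold and 110-fold from 20 to 100 kb, 2.04-fold and 32.1-fold from 100 to 500 kb, and 1.30-fold and 12.4-fold from 500 kb to 1 Mb. Over 1 Mb it was 1.07-fold in the dilution library and 5.06-fold in the in situ 200k library. In the in situ 1k library it was 7.98-fold under 20 kb and 1.04-fold over 1 Mb.

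**Figure D2:**
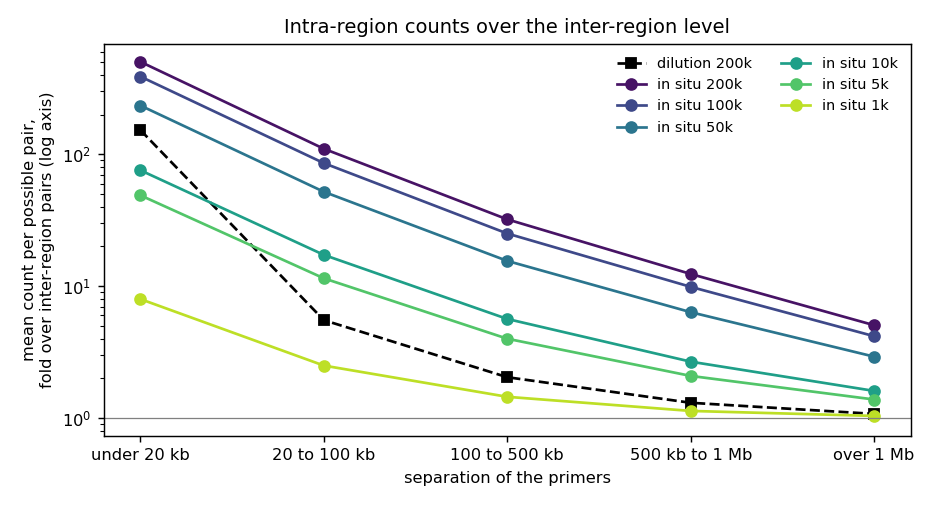
Lines show the mean count per possible intra-region pair over that per inter-region pair (log axis), by separation of the primers, for the dilution library (black) and the 6 in situ libraries. From 100 to 500 kb the in situ 200k library is at 32.1-fold and the dilution library at 2.04-fold.

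After all libraries were thinned to 7758477 intra-region counts, the dilution library detected 23.8% of the 2165417 intra-region primer pairs seen in any library, and the in situ 200k library detected 41.4%. The difference was −17.6 percentage points. This depth includes same-fragment pairs, which held most intra-region counts of the dilution library only. For forward and reverse pairs of different fragments, thinned to 5920215 counts and taken over all 1433779 possible pairs, the difference was −5.46. That rule was added after the data had been seen and changes the pairs, the depth and the denominator together. At that depth, 485802 fragment pairs at 40 kb or more had 2 orientations. Both were detected in 185119 in the dilution library and 174799 in the in situ 200k library, and only 1 in 175049 and 178364. The 1% of detected intra-region pairs with most counts held 84.9% of the thinned counts in the dilution library and 22.6% in the in situ 200k library, and 54.6% and 21.3% for forward and reverse pairs of different fragments thinned to 5920215 counts.

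In the maps that the authors normalized together, the distance-corrected values of the dilution and in situ 200k libraries correlated across 4-kb bin pairs with a Spearman rho of 0.411. Bin pairs are not independent replicates. The rho was 0.468 at Sox2, 0.372 at Klf4, 0.466 at Dppa2, 0.459 at Zfp42 and 0.498 at Nanog. On raw counts per bin pair it was 0.648, and it was 0.737 without the distance correction.

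A contact cluster was a group of at least 3 adjoining bin pairs with the authors' p under 0.01 at 40 kb or more. The dilution library had 1179 clusters and the in situ 200k library had 409. There were 257 and 64 at Sox2, 755 and 300 at Klf4, 70 and 14 at Dppa2, 75 and 22 at Zfp42, and 22 and 9 at Nanog. The median span was 968 kb for the dilution clusters and 1452 kb for the in situ clusters, and 48.8% and 66.3% spanned over 1 Mb. At the authors' p under 0.001 there were 132 and 64 clusters. The maps were not matched in depth, so these numbers cannot be read as numbers of contacts. A dilution cluster at p under 0.01 held a median of 15 forward and reverse counts, and an in situ cluster 102. Any such count was present in 1142 dilution and 401 in situ clusters.

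Of the dilution clusters, 190 (16.1%, 95% Wilson interval 14.1 to 18.3) overlapped an in situ 200k cluster, against a mean of 1.78% and a highest value of 3.31% over 100 random shifts of the in situ clusters along the diagonal. Of the in situ clusters, 192 (46.9%, interval 42.2 to 51.8) overlapped a dilution cluster, against a mean of 5.19% and a highest value of 8.07%. The intervals over clusters in this paragraph treat clusters as independent, although several shared a bin, and can be too narrow. The shared part of the dilution clusters was 14.8% at Sox2, 17.4% at Klf4, 7.14% at Dppa2, 14.7% at Zfp42 and 22.7% at Nanog. The share was 29.3% with clusters called at p under 0.05 and 8.74% when at least 50% of a cluster's bin pairs had to overlap. The shifts keep distance but move calls off the bins with few primers, where clusters of both libraries lay. They therefore cannot tell shared contacts from a shared primer layout. In the map of the in situ 1k library, 9.16% of the dilution clusters overlapped a cluster, against at most 3.82% over shifts. At the summits of the dilution clusters, the median log2 enrichment over the local background was 3.07 in the dilution map and 0.47 in the in situ 200k map. The median difference was −2.63 (95% bootstrap interval −2.70 to −2.57), at places chosen in the dilution map. At the summits of the in situ clusters the median was 1.64 in the in situ map and 1.96 in the dilution map, and with clusters called at p under 0.05 it was 1.17 and 1.05, the opposite order. Relative to each map's median bin pair, the dilution map was higher at these summits in both cases, by a median of 0.67 and 0.32 on the log2 scale. Over all bin pairs the log2 enrichment had an SD of 1.14 in the dilution map and 0.56 in the in situ map, so equal enrichments stood at different heights over the scatter.

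The 3 clusters with the lowest p per region and library were named by rule, 30 in all. At Klf4, 1 cluster ranked first in both libraries. It joined 54079137 to 54083136 with 56431137 to 56435136 over 2352 kb, with a log2 enrichment of 5.57 and p of 1.9e-05 in the dilution library and 4.69 and 8.98e-09 in the in situ 200k library. It held 455 counts in the dilution library and 1368 in the in situ library, and 1 primer pair held 92.1% and 84.4% of them. At Sox2, the bin from 33598317 to 33602316 met the bin from 35082317 to 35086316 over 1484 kb, with a log2 enrichment of 4.78 in the dilution and 3.49 in the in situ library. At Zfp42, a cluster at 44691236 to 44695235 and 44775236 to 44779235 spanned 84 kb, with a log2 enrichment of 4.04 in the dilution and 2.02 in the in situ library. It held 553 counts in the dilution library and 1260 in the in situ library over 7 primer pairs. At Nanog, the bins from 122141032 to 122145031 and from 122557032 to 122561031 met over 416 kb, with a log2 enrichment of 3.46 in the dilution and 2.94 in the in situ library, on 3 counts in the dilution cluster. At Dppa2, the cluster ranked first in situ joined 48324556 to 48328555 with 49168556 to 49172555 over 844 kb, with a log2 enrichment of 2.66 in the in situ library and 3.06 in the dilution library. The 3 named dilution clusters at Dppa2 rested on 14, 6 and 7 counts, and none overlapped an in situ cluster. Of the 15 named clusters of each library, 8 of the dilution library and 11 of the in situ library overlapped a cluster of the other, and 5 and 7 spanned over 1 Mb.

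Clusters lay where primers were sparse, with a mean of 1.32 primers per 4-kb bin in dilution clusters and 1.39 in in situ 200k clusters, against 2.10 and 2.04 in boxes of the same size and distance moved elsewhere in the region. The double alternating design placed primers at both ends of 1867 of 2678 fragments and at 1 end of the other 811 (30.3%). The primer pair with most counts in a cluster used a fragment with 1 primer in 1074 of 1142 dilution clusters (94.0%, 95% Wilson interval 92.5 to 95.3) and in 305 of 401 in situ 200k clusters (76.1%, interval 71.6 to 80) that held counts. In the moved boxes the share was 24.7% (22.3 to 27.3) and 35.2% (30.7 to 40). It was 30% of all possible pairs. Among the named clusters it was so in 15 of 15 from the dilution library and 13 of 15 from the in situ library. The leading pair held a median of 50% of a dilution cluster's counts and 38.7% of an in situ cluster's, against 14.0% and 13.3% in moved boxes. The moved boxes were matched on size and distance but not on primers or counts. Fewer primers or counts alone can raise the leading pair's share and the part that uses a fragment with 1 primer. The contrasts therefore cannot be told apart from the sparse primers. The intervals treat clusters as independent, although several shared a bin. These measures were added after the clusters had been seen.

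**Figure D3:**
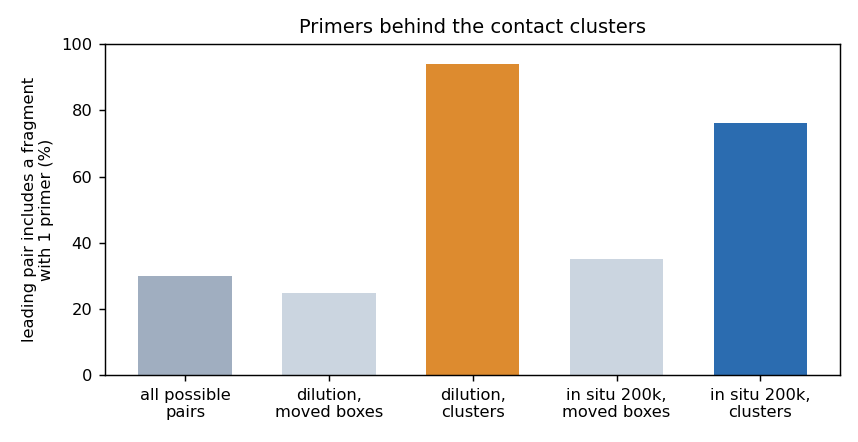
Bars show the percent of clusters, of moved boxes of the same size and distance, and of all possible pairs, in which the leading primer pair includes a fragment with 1 primer. The share is 94.0% in dilution clusters and 76.1% in in situ 200k clusters, against 30% of all possible pairs.

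The in situ series asked how the measures changed with the number of genome copies from 200000 to 1000. Inter-region pairs held 8.77%, 11.3%, 16.6%, 33.7%, 41.9% and 65.5% of counts in order of falling input. Among forward and reverse pairs of different fragments that touched a region, the share went from 11.8% to 69.1% at Klf4, from 15.6% to 79.7% at Sox2, from 20.6% to 89.2% at Dppa2, from 20.8% to 89.4% at Zfp42 and from 22.1% to 92.2% at Nanog between the in situ 200k and 1k libraries. The share of all counts rose as the input fell (Spearman rho −1, two-sided exact permutation p = 0.0028, the smallest that rho over 6 libraries can give; adjusted p = 0.00972 over 7 measures). Pearson's r with log10 genome copies was −0.988 (exact permutation p = 0.00139, adjusted p = 0.00486) and −0.998 without the in situ 200k and 1k libraries. With 5 libraries rho stayed −1, and the adjusted p was 0.0583 without the in situ 200k, 10k or 5k library. The exact p values measure only the order and spread among these libraries.

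The in situ maps became less like the dilution map at lower input. Their Spearman rho with it was 0.421, 0.402, 0.388, 0.259, 0.213 and 0.0826 in order of falling input, and it fell with the genome copies (rho 1, exact permutation p = 0.0028, adjusted p = 0.00972; Pearson's r 0.988, exact permutation p = 0.00139, adjusted p = 0.00486, and 0.990 without the in situ 200k and 1k libraries). On raw counts per bin pair the rho with the dilution map was 0.648, 0.627, 0.602, 0.490, 0.475 and 0.419. Depth changed along with input, with 36696828 intra-region forward and reverse counts of different fragments at 200000 copies and 7542981 at 1000. With all libraries thinned to 5920215 such counts, at 40 kb or more, the raw rho was 0.574, 0.560, 0.538, 0.427, 0.411 and 0.385. For the normalized maps, which were not matched in depth, the adjusted p was again 0.0583 without the in situ 200k, 10k or 5k library. Against the in situ 200k map of the same joint normalization, rho was 0.755 for the in situ 100k, 0.686 for the 50k, 0.399 for the 10k, 0.304 for the 5k and 0.0941 for the 1k map. At 1000 copies this rho was 0.0829 at Klf4, 0.0961 at Sox2, 0.0986 at Dppa2, 0.145 at Zfp42 and 0.179 at Nanog. The median log2 enrichment at the summits of the dilution clusters was 0.60, 0.52, 0.53, −0.10, −0.55 and −1.64 (rho 0.943, exact permutation p = 0.0167, adjusted p = 0.0389; Pearson's r 0.958, exact permutation p = 0.00278, adjusted p = 0.00648, and 0.967 without the in situ 200k and 1k libraries). Relative to the median bin pair of each map, which went from −0.07 to −0.96, the enrichments were 0.66, 0.60, 0.62, 0.17, −0.15 and −0.69. The call was lost without the in situ 200k, 10k, 5k or 1k library (adjusted p from 0.0833 to 0.194) and with dilution clusters called at p under 0.001 (rho 0.771, exact permutation p = 0.103).

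**Figure D4:**
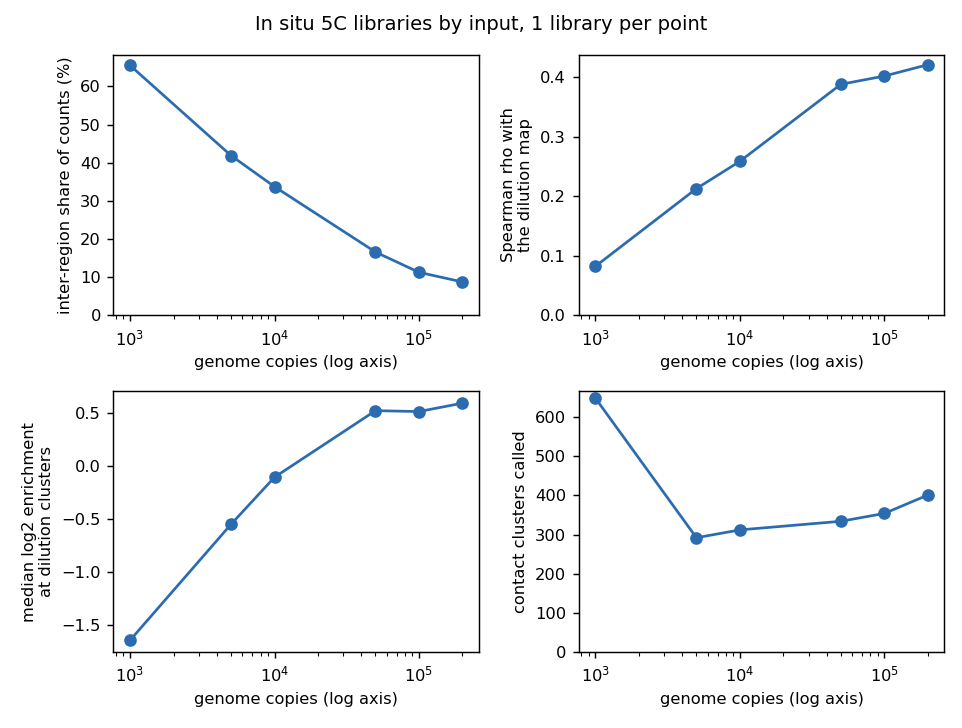
Each point is 1 in situ library, plotted against its genome copies (log axis), for the inter-region share of counts, the Spearman rho with the dilution map, the median log2 enrichment at dilution clusters and the number of clusters. From 200000 to 1000 copies the inter-region share goes from 8.77% to 65.5% and the rho from 0.421 to 0.0826. The maps are not matched in depth.

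The other 4 measures did not pass the test with the thresholds given above. Of the dilution clusters, 11.6%, 9.50%, 9.84%, 7.89%, 7.63% and 9.16% overlapped an in situ cluster in order of falling input (rho 0.771, exact permutation p = 0.103, adjusted p = 0.144; Pearson's r 0.679, exact permutation p = 0.129). With clusters called at p under 0.001, rho was 0.899 and passed (exact permutation p = 0.0278, adjusted p = 0.0486). The mean over shifts was 1.97% at 200000 copies and 2.58% at 1000 copies. The number of clusters was 401, 354, 334, 312, 292 and 648 (rho 0.143, exact permutation p = 0.803, adjusted p = 0.919; Pearson's r −0.505, exact permutation p = 0.324). Without the in situ 1k library rho was 1 with an adjusted p of 0.0389, and with clusters called at p under 0.05 in all 6 libraries it was −1, the opposite direction, with an adjusted exact permutation p of 0.00648. The detected intra-region pairs, thinned, were 41.4%, 40.3%, 37.5%, 24.8%, 26.3% and 30.4% (rho 0.771, exact permutation p = 0.103, adjusted p = 0.144; Pearson's r 0.801, exact permutation p = 0.0819). With at least 2 counts per pair rho was 1 (adjusted p = 0.00648). The top 1% of intra-region pairs held 22.6%, 21.9%, 20.6%, 16.0%, 16.6% and 23.7% (rho 0.0857, exact permutation p = 0.919; Pearson's r 0.189, exact permutation p = 0.685). Its rho was −0.1 without the in situ 200k, 100k or 50k library. Without both the in situ 200k and 1k libraries, Pearson's r of these 4 measures was 0.940 for the overlap, 0.989 for the number of clusters, 0.957 for the detected pairs and 0.956 for the top 1%.

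A named dilution cluster counted as called in an in situ library where any of its bin pairs lay in a cluster there. Unlike the enrichments of named clusters given above, those in the series are relative to the median bin pair of each map. That median went from −0.07 at 200000 copies to −0.96 at 1000, which raises the values most at 1000 copies. Of the 15, 2 were called in all 6 in situ libraries, 1 in 5, 3 in 3 or 4, 2 in 1 or 2, and 7 in none, of which 4 had a summit outside the bin pairs of the series. The 84-kb Zfp42 cluster was called in all 6, with a log2 enrichment of 1.61 at 200000 copies, 1.53 at 5000 and 3.9 at 1000 at its summit, where the authors' p was 0.0153 at 50000, 0.0543 at 10000 and 0.0764 at 5000 copies and so not under 0.01. The other was a Klf4 cluster at 53951137 to 53955136 and 55571137 to 55575136, over 1620 kb, with a log2 enrichment of 2.27 at 200000 copies and 7.19 at 1000. The 2352-kb Klf4 cluster was called in 5 and missed in the in situ 100k library, with a log2 enrichment of 4.51 at 200000 copies, 1.30 at 100000, 5.32 at 50000 and 6.55 at 1000. Over all bin pairs the SD of the log2 enrichment was 0.61 at 200000 copies and 1.62 at 1000.

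The primer lists compared the double alternating design with a single alternating one over the 3 regions that both cover. Within them the double design had 1458 primers on 838 fragments and the single design 664 primers on 664 fragments. The double design allowed 187881 forward and reverse pairs and the single design 38781, a ratio of 4.84. The ratio was 4.52 at Sox2, 5.38 at Klf4 and 4.37 at Nanog. In distinct fragment pairs the numbers were 118832 and 38781, a ratio of 3.06. The series holds no library labelled with the single design, so the designs were compared on their lists alone.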

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

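The tests of the contact clusters and of the dilution map were written down before their values were known, but after the clusters and the excess of single-primer fragments had been seen; the moved-box comparison and both tests of the inter-region share were chosen after the results were seen.

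Pairs of primers with the same direction, which the ligation step cannot join as designed, held 3.93% of counts in the dilution library. They held 1.15%, 2.05%, 2.30%, 1.43%, 2.52% and 2.81% in the in situ libraries from 200000 to 1000 copies. They are listed because the design should give none, which is no test of their size. They are part of the inter-region share of all counts and of the detected intra-region pairs, and are left out where only forward and reverse pairs were counted. The dilution map that the authors normalized separately had 354 clusters, over a smaller part of the Sox2 and Klf4 regions than the joint map. In the 3 regions where its bins align with the joint map it had 254 clusters and the joint dilution map had 167, and 157 of the 254 (61.8%) overlapped one of the joint map.

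Explanations were weighed for the contact clusters of the in situ 200k library, and counting noise was tested on those over 1 Mb in the map of the input series. Of these, 84 of 321 (26.17%) were called again in the in situ 100k library, against at most 6.854% over 100 shifts. That was the outcome set beforehand against noise. The shifts move calls off the bins with few primers, where clusters lay, so noise that gathers in such bins could pass them too. In the in situ 1k library 9.66% were called again, against at most 5.92%. The test therefore cannot decide on noise, and a primer effect would recur in the same way. Fragments with primers at both ends allow a second orientation of the leading pair, and in the 96 clusters that had one its median count was 2.221% of the leading one (bootstrap interval 0.645 to 4.35), under the 10% set beforehand and below the 8.33% (6.35 to 10.7) of moved boxes, which themselves passed that bound. The leading pair was picked for its high count, and the moved boxes were not matched on that count. A low ratio can follow from that choice alone, so it cannot decide. The deposited signal per raw count was 6.012 times higher in bin pairs with 1-primer than with 2-primer fragments, but balancing gives such a ratio by construction (mean raw counts 26.7 and 153, mean signals 417 and 397; in the dilution map the signals were 482 and 266 and the ratio 13.0), so this decides nothing about balancing as a cause, which cannot be told apart. A test of whether 1 primer pair held most of the counts of the named in situ clusters gave a median of 55.8% (45.5 to 71.5), which left open the bound of 50% set beforehand, and it was set aside after that value was seen. That the counts of a cluster belong to 1 primer pair may hold for part of the clusters and stays a hypothesis; no biological explanation was tested.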

How the results depend on the processing

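Of 104 alternatives, 57 did not turn the direction and kept the side of the threshold or value, 28 moved the value, 11 lost a call, 3 gained one and 5 turned the direction. The 57 include trends of the number of clusters and of the top 1% whose rho was 0 with 1 library left out, which have no direction. The alternatives restricted to forward and reverse pairs of different fragments and those relative to the median bin pair were chosen after seeing the data. The cause of a change was not tested unless stated. The inter-region difference of 7.06 points was 6.04 with at least 2 counts per pair, 51.1 without the top 1% of pairs, 12.5 with pairs counted once and 30.5 among forward and reverse pairs. The difference in detection was −14.8 without thinning, −21.0 with at least 2 counts, −16.4 at 200 kb or more and −5.46 among forward and reverse pairs, which also changed the depth and the denominator. The map correlation was 0.737 without distance correction, 0.648 on raw counts and 0.574 on thinned forward and reverse counts. With p under 0.05, p under 0.001, at least 1 and at least 5 bin pairs, there were 2988, 132, 1950 and 779 dilution clusters and 1789, 64, 841 and 244 in situ clusters, as the rules themselves admit more or fewer. The shared part was 29.3% at p under 0.05, 22.0% at p under 0.001, 22.0% within 2 bins and 8.74% when at least 50% of the bin pairs overlapped. The enrichment difference was −2.02 and −3.49 with these p thresholds, −2.48 with 1 and −2.71 with 5 bin pairs, and −3.12 relative to the median bin pair; at in situ clusters, the dilution median of 1.96 against 1.64 in situ turned to 1.05 against 1.17 at p under 0.05, but not relative to the median bin pair (dilution higher by 0.67 and 0.32). The trend of detected pairs had rho 1 with at least 2 counts (adjusted exact permutation p = 0.00648). The trend of clusters had r −0.505 by Pearson and rho −1 at p under 0.05, the opposite direction, which passed the test (adjusted exact permutation p = 0.00648). Recovered dilution clusters had rho 0.899 at p under 0.001 and then passed (adjusted exact permutation p = 0.0486), while their enrichment had rho 0.771 at p under 0.001 and did not. With each in situ library left out in turn, rho ranged from −1 to −1 for the inter-region share, from 1 to 1 for the map correlation, from 0.9 to 1 for the enrichment, from 0.6 to 0.9 for detected pairs, from −0.1 to 0.9 for the top 1%, from 0 to 1 for clusters and from 0.6 to 0.9 for recovered clusters. Fewer libraries raise the smallest exact permutation p of rho from 0.0028 to 0.0167. The call was lost without the in situ 200k, 10k or 5k library for the inter-region share and the map correlation (adjusted p 0.0583 with 5 libraries), and without the in situ 200k, 10k, 5k or 1k library for the enrichment; the cluster trend passed without the in situ 1k library. The primer design ratio was 4.86 at 40 kb or more. No paired analysis was possible because each group has 1 library. Promoter contacts and 2 alternatives of them were not run, because the annotation is on another build than the maps. Counting error of the shares is at most 0.1 percentage points at this depth, and the spread between replicates is unknown.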

Other observations

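The tests of the inter-region share below were chosen after the result was seen; those of the dilution map were not, except for the thinning within distance classes.

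Some bins were at the summit of several clusters, and the bin with most summits of each library is given for each region. At Klf4 the bin from 54843137 to 54847136 led in both libraries, with 46 dilution and 16 in situ 200k summits. At Sox2 the bin from 33602317 to 33606316 led in the dilution library with 26 dilution and 6 in situ summits, and that from 35506317 to 35510316 led in situ with 23 and 8. At Dppa2 the bin from 49076556 to 49080555 led in the dilution library with 14 and 0, and that from 48020556 to 48024555 led in situ with 4 and 3. At Zfp42 the bin from 44219236 to 44223235 led in the dilution library with 11 and 1, and that from 44159236 to 44163235 led in situ with 0 and 4. At Nanog the bin from 122333032 to 122337031 led in the dilution library with 4 and 0, and that from 122141032 to 122145031 led in situ with 2 and 3.

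The 2 orientations in which a pair of fragments with primers at both ends can be read agreed less at low input. Over 485802 such pairs after thinning, their counts correlated with a Spearman rho of 0.381 in the dilution library and 0.398, 0.365, 0.294, 0.0802, 0.0360 and 0.00831 in the in situ libraries from 200000 to 1000 copies. The in situ 200k library had 409 clusters in the joint map with the dilution library and 401 in the input series, and 281 (68.7%) of the 409 overlapped. The pair with most counts was a same-fragment pair in the dilution library and an inter-region pair in each in situ library, with 142641 counts, or 142.6 per genome copy, in the in situ 1k library.

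The raw dilution map correlated less with the in situ 200k map than the in situ 100k map did. With the in situ 100k and 200k libraries both thinned to the dilution library's 5920215 forward and reverse counts, the in situ 100k map still correlated with a rho higher by 0.06568 (0.0658 to 0.0687 over 5 other draws), above the 0.05 set beforehand and under the 0.1276 with neither thinned. The in situ 100k library was thinned instead to the dilution library's counts within each region and class of distance, with 2191639 counts at 40 kb or more in both. With the in situ 200k library thinned as before, the rho was higher by 0.0656 to 0.0676 over 5 draws. Depth in reads alone thus does not account for the difference between these single libraries, and the spread between replicates is unknown. The raw maps were corrected for distance but not for primers per bin, which all libraries share. The thinned in situ 1k map still had a rho of 0.379 with the thinned in situ 200k map. The dilution map's rho of 0.5738 lay above the 0.4564 and 0.425 of the thinned in situ 10k and 5k maps. Among forward and reverse pairs of different fragments, their inter-region shares of 33.6% and 41.5% lie on either side of its 38.8%. Among all counts, their shares of 33.7% and 41.9% both lie above its 15.8%. Neither outcome set beforehand was met, and since the protocol differs along with the share, the part of the share cannot be told apart; no biological explanation was tested, since the cells were of 1 line and condition.

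The inter-region share rises as the genome copies fall. A few primer pairs with very many reads would leave no trend with each pair counted once, but rho was then still −1 (exact permutation p = 0.0028). Among forward and reverse pairs of different fragments the share counted once went from 54.5% at 200000 copies to 70.9% at 1000. By counts it went from 8.28% to 65.4%. The share counted once has a ceiling set by the 3727908 inter-region and 1433779 intra-region possible pairs, and it was not thinned. Its smaller rise therefore does not measure the part of a few pairs. The order thus does not rest on a few pairs. Without the 1% of pairs with most counts in each library, the share of all counts was 12.9%, 16.7%, 24.4%, 41.7%, 49.0% and 66.2% in order of falling input. With those pairs it went from 8.77% to 65.5%. The values argue against these pairs as the main source of the rise in these libraries. A constant amount of random product would give a slope of −1 for log10 random over specific product against log10 copies, if the specific product is in proportion to the copies. The slope was −0.7962 (−0.852 to −0.660 with each library left out). Under that assumption, which was not tested, the slope argues against a constant amount as the whole cause. The ratio did not follow 1 slope, since it went from 1.43 to 10.4 between 5000 and 1000 copies, more than in proportion, so no other explanation is put forward; the design gives no biological one.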
